A study of Homo sapiens with 6 samples.

How the data were processed

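Caco-2 cells, an established human line from a colorectal carcinoma that is widely used as a model of the intestinal epithelium, were grown with 10% fetal bovine serum and either left untreated or given 1 mM carnosine (the dipeptide beta-alanyl-L-histidine) for 3 days, per the labels' protocols. The labels describe 3 independent experiments and number the 3 samples of each group 1 to 3, 1 array each. They do not state that a number stands for 1 experiment, and same-numbered samples are called an experiment here because of the pairing check below. Total RNA was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays. Per the file headers, each array held 43118 spots of 34127 gene probes of 60 bases beside 1377 control spots. The 6 arrays lay on 2 slides. Slide 1 held experiment 1 (2 arrays) and slide 2 held experiments 2 and 3 (4 arrays), so each slide held both groups.

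The scanner images were quantified with Agilent Feature Extraction 10.7.1.1, per the file headers, while the submitters' processing notes name version 9.5.1.1. The deposited scanner files give spot intensity on a linear scale. The processed signal is intensity after background subtraction and spatial detrending within the array, with no normalization between arrays, per the file headers. Deposited flags per spot, which carry no physical unit and are another kind of value, mark spots as well above background, saturated, non-uniform or outlying, per the file headers. The authors also deposited a value table of 34127 probes in which all 6 columns have a median intensity of 109.6. Each column correlated across probes with the log2 processed signal of its own array at Pearson r between 0.9993 and 0.9998. The values of that table are linear, quantile-normalized and not centred per gene, as judged from the values; the steps by which the authors made it are not given in the sources used here.

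The analysis started from the log2 processed signal minus the 75th percentile of each array (0.75 quantile over spots that are not controls). Non-uniform and outlying spots were set to missing. They made up 0.62% to 1.12% of spots per array. Spots of 1 probe were averaged. Probes were kept if well above background on at least 3 of the 6 arrays and measured on at least 2 arrays of each group, which left 23542 probes. Gene names were updated through the RefSeq accession of each probe, without version, with the RefSeq gene table of assembly GRCh38.p14, used for names and gene classes only. Of the 34127 probes, 25715 matched and 8412 kept the name in the file. For each gene the probe with the highest mean was used, giving 18229 genes, of which 15520 carried a gene symbol. Probe positions are those in the files, on build hg19.

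Carnosine and control were compared with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) on the log2 scale, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. As fixed before the data were examined, the design held the group alone, and the fit with the experiment number as a replicate block was an alternative. The same-numbered samples were then checked for pairing. Deviations from the group means, over all genes, correlated between the control and carnosine arrays of the same experiment at 0.88, 0.61 and 0.74 for experiments 1, 2 and 3. The highest value with an array of another experiment was -0.63, 0.2 and 0.39. Experiment 1 was the only pair on slide 1, so its values cannot tell a shared experiment from a shared slide. Only the values of experiments 2 and 3, both on slide 2, bear on pairing apart from the slide. On this ground the same-numbered samples were treated as pairs. Values with the replicate block are printed beside those without it wherever a call or count changed.

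A total of 38 gene lists holding 975 entries were written before the data were examined, and each had at least 5 measured members. Each was tested with limma's camera at a preset correlation between genes of 0.01, over the 18221 genes measured on all 6 arrays. Camera with an estimated correlation and fry stand beside it. The run with an estimated correlation differs from the preset run in more than the correlation. For the inflammatory list without the block, the estimate of 0.002 lay below the preset 0.01. Its unadjusted p in camera still rose from 0.00325 to 0.0341. A list that fails with an estimated correlation is therefore not read as one undone by correlation between its genes. Genes were named by a rule fixed before the data were examined. Per direction it takes the 12 genes of largest change among those past the threshold with the same direction in all 3 experiments. Where fewer passed, places were filled by the smallest unadjusted p among genes changed at least 1.5-fold the same way in all 3 experiments. It adds all measured genes of carnosine and histidine dipeptide handling, 6 genes chosen beforehand (BDNF, GDNF, VEGFA, SIRT1 and PDK4 among them) and up to 4 genes per other list with the largest change. GDNF was below the filter. Some genes that the rule names are not reported here, though they stay in the tests and counts. A gene not well above background on every array of a group was given a bound: the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

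The alternatives fixed at the same time covered the replicate and slide blocks, slide 2 alone, each array left out, array weights, trended and robust eBayes, normexp background correction with an offset of 50, quantile and median scaling, 2 other filters on dim probes, flagged spots kept, the mean of all probes of a gene, single probes and the authors' value table. The slide 2 files hold no mean spot signal, so normexp was run on the median signal of all arrays, a departure from the mean signal intended. On the carnosine array of experiment 1, 16 spots had a local background over 10 times the array's median, and no other array had any. With these spots in, the normexp estimate of mean background for that array was -1020, against -1.69 to 2.53 on the other arrays, and the median log2 ratio of all genes moved from 0.01 to 0.26. A second normexp run without these spots was added after that result was seen. Both runs are reported, and the run with all spots is the one fixed beforehand. Also added after seeing the data were a correction of each array for probe GC content (loess, span 0.3) and the other processing alternatives within the fit with the replicate block.

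The tests were run on simulated data built from the real gene levels and residuals of 18221 genes. Of 100 genes changed by 2 on the log2 scale, 31% were called without the replicate block and 81% with it. Of 100 genes changed by 1, 0% and 40% were called. No unchanged gene was called in either fit. Of 2 simulated lists shifted by 0.4, camera called 2 in each fit and no other list. Residual signs were drawn at random for each gene and array, so simulated genes were not correlated within a list. The simulation therefore does not show how often camera calls lists of correlated genes. In the real data without the replicate block, the estimated correlation was 0.544 for DNA replication. The 75th percentile of the processed signal ranged from 1058 to 1915 between arrays, and 66.2% to 71.9% of probes were well above background. Saturation affected 1 spot on 1 array. With 3 arrays per group, the number of arrays limits the precision, and an exact permutation test of a single gene cannot give a two-sided p below 0.1. Figures were drawn with matplotlib.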

Results

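Gene expression was measured in Caco-2 cells cultured for 3 days with 1 mM carnosine or without it, with 3 control and 3 carnosine samples from 3 independent experiments. A control and a carnosine sample of the same number are called an experiment here, which rests on the likeness of their signals and not on a label. The comparison asked which genes differ in level between treated and untreated cells. Signals of 18229 genes were tested. Between 66.2% and 71.9% of probes were well above background on each array. Correlations of log2 signal between arrays were 0.981 to 0.991 within an experiment, 0.988 to 0.989 within a group on slide 2, and 0.960 to 0.968 within a group across slides. The first principal component held 58.3% of the variance and separated the slides. The second held 23.3%, and on it each carnosine array lay below the control array of its experiment.

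Carnosine-treated cells had higher levels of WFIKKN1, TSHR, MIA and TLR3 and lower levels of LHPP, KCNQ1OT1 and MRPL23-AS1 in each of the 3 experiments. WFIKKN1, which encodes a secreted protease-inhibitor protein that binds growth factors of the TGF-beta family, had a mean log2 ratio of 2.81 ± 0.21 (SD, n = 3). Its signal was not well above background on any control array, so the difference was at least 6.61-fold. LHPP, a phosphatase of histidine and lysine residues, had a log2 ratio of -3.91 ± 0.83 (SD, n = 3), the lowest mean among the genes named by the rule. In the limma fit without the replicate block, WFIKKN1 alone passed (adjusted p = 0.0449), with 2135 genes at unadjusted p below 0.05. If no gene differed and the arrays were independent, 911 would be expected. Wrong splits of the arrays that kept slide 1 together gave 1375 to 3584 such genes. Wrong splits that parted slide 1, as the real split does, gave 21 to 268. The value of 911 therefore does not serve as a chance level for these arrays. With the replicate block, 1132 genes were higher and 1215 lower at adjusted p below 0.05, 12.9% of those tested.

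Hereafter a gene is said to have risen or fallen where it passed with the replicate block, and it did not pass without the block unless it is WFIKKN1. Without experiment 1 the count with the block was 609 genes, without experiment 3 it was 582, and without experiment 2 limma called 0 genes, with 4653 at unadjusted p below 0.05. It was also 0 when dim probes were not filtered out, with 5249 at unadjusted p below 0.05, and with normexp background correction over all spots, with 579. Normexp without 16 smeared spots of 1 array gave 3050 genes, 1448 higher and 1602 lower. With the slide as the block, 380 genes were higher and 561 lower. On slide 2 alone, with 2 arrays per group and no replicate block, limma called 0 genes, with 2801 at unadjusted p below 0.05; slide 1 held 1 array per group and allowed no test. Of the genes that passed with the replicate block, 202 were at least 2-fold higher and 348 at least 2-fold lower, and the median absolute log2 ratio was 0.726.

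Among the genes named as higher, TSHR, the thyrotropin receptor, rose (log2 ratio 3.07 ± 0.33, SD, n = 3; adjusted p = 0.0111 with the replicate block and 0.0596 without). It was not well above background on any control array, which gives a bound of at least 2.0-fold. MIA, a small secreted protein first described in melanoma cells, rose by 2.53 ± 0.24 (SD, n = 3), and its probe lies on chromosome 19 at 41282959 to 41283335. TLR3, the endosomal receptor for double-stranded RNA, rose by 2.26 ± 0.36 (SD, n = 3). The potassium channel gene KCNJ14 rose by 2.16 ± 0.18 and TCHH, which encodes trichohyalin, by 2.05 ± 0.37 (SD, n = 3). DLG2, a synaptic scaffold gene, had a log2 ratio of 2.03 by its brighter probe and 1.48 by its other probe. BNIPL, ESS2 and ARHGDIB rose by 1.98, 1.81 and 1.67. DOK3, an adaptor protein, gave 1.86 by its brightest probe, but its other probes gave 0.20 and -0.34 and did not pass.

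Among the genes named as lower, LHPP fell on each of its 2 probes, with log2 ratios of -3.91 and -2.06. The probe used for LHPP lies on chromosome 10 at 126302618 to 126302677. KCNQ1OT1, a long noncoding RNA of the imprinted region of chromosome 11 (probe at 2661803 to 2661862), had a log2 ratio of -3.26 ± 0.91 (SD, n = 3). MRPL23-AS1, an antisense transcript on the same chromosome (probe at 2004439 to 2004498), had -2.89 ± 0.40 (SD, n = 3). For both RNAs the adjusted p was 0.0596 without the replicate block; with it, the adjusted p was 0.0164 for KCNQ1OT1 and 0.0111 for MRPL23-AS1. DNAI4, a dynein arm gene, had a measured ratio of -2.33 and was not well above background on any carnosine array, so it was at least 1.49-fold lower. GPR143, a pigment cell receptor, had a log2 ratio of -2.31, CACNG6, a calcium channel subunit, -2.18, and the sugar phosphate exchanger SLC37A2 -2.03 (-1.04 by its other probe, which did not pass); by the probes used, all 3 passed with the replicate block. VMAC, B9D1, SLC44A5 and LRRC3 had log2 ratios of -1.93, -1.88, -1.63 and -1.36, and all 4 passed with the replicate block. The ratios of SLC44A5 and DNAI4 turned positive with normexp over all spots but not without the smeared spots.

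**Figure D1:**
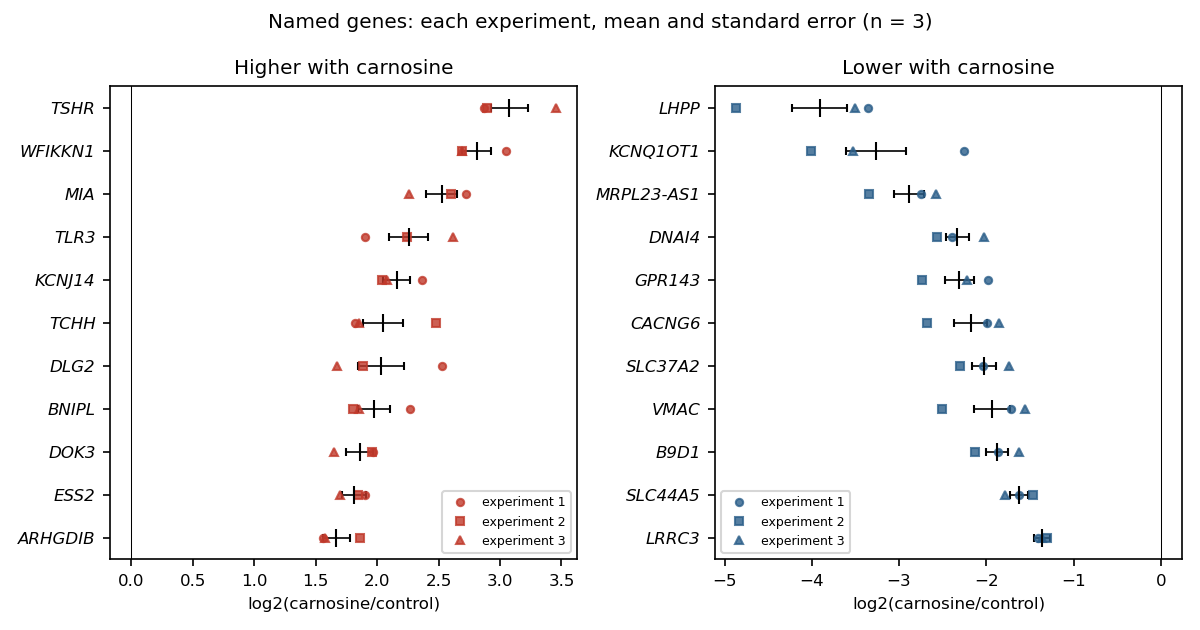
Log2 ratio of carnosine to control for genes named as higher (left) and lower (right); symbols are the 3 experiments, and the vertical tick with its bar is the mean and standard error from the limma fit with the replicate block (n = 3). All symbols of a gene lie on the same side of 0, with means from 1.67 (ARHGDIB) to 3.07 (TSHR) and from -1.36 (LRRC3) to -3.91 (LHPP). The ratios of WFIKKN1, TSHR and DNAI4 are as measured, with 1 group not well above background.

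The 3 experiments gave similar ratios across genes. Experiment 1 correlated with experiment 2 at Pearson r = 0.611 and with experiment 3 at 0.575, and experiments 2 and 3, on the same slide, at 0.593 (across genes, which are not independent replicates). Of 18221 genes with 3 ratios, 58.2% had the same sign in all 3. A change of at least 1.5-fold in the same direction in all 3 experiments was found for 418 higher and 618 lower genes, 1036 in all. With the sign of experiment 1, 2 or 3 turned, the totals were 16, 9 and 20. At 2-fold, the total was 277 as measured and 3, 1 and 4 with a sign turned. No p-value is attached to these counts.

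**Figure D2:**
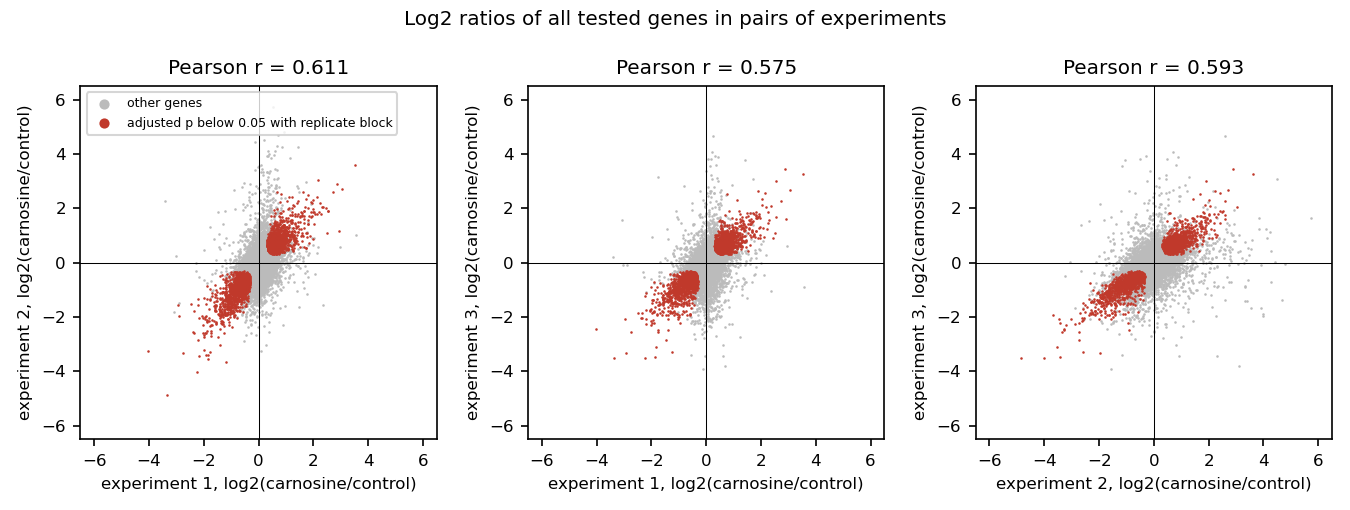
Each point is a gene, plotted by its log2 ratio of carnosine to control in 1 experiment (horizontal axis) and another (vertical axis). Genes that passed with the replicate block are red and lie in the lower left and upper right quadrants; Pearson r across genes is 0.611, 0.575 and 0.593.

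**Figure D3:**
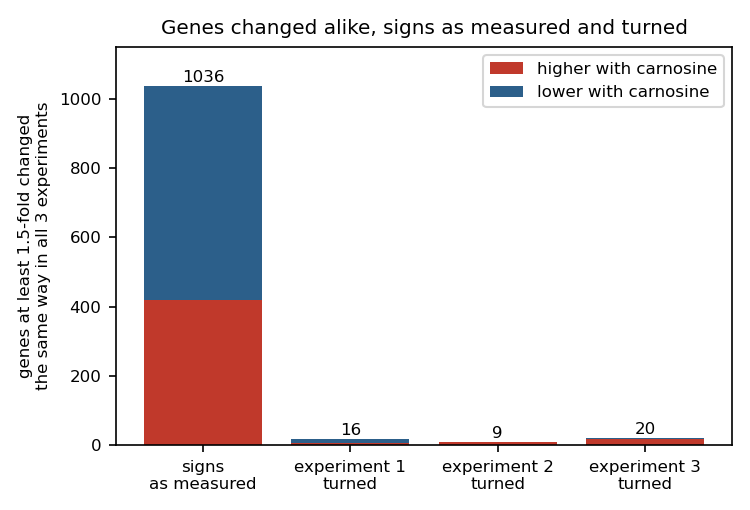
Number of genes changed at least 1.5-fold in the same direction in all 3 experiments, as measured (418 higher in red and 618 lower in blue) and with the sign of 1 experiment turned (16, 9 and 20 in all). Where a sign is turned, red and blue refer to the direction after turning.

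Genes of the mature enterocyte were lower with carnosine as a group. Of 31 measured genes of enterocyte differentiation, 7 fell, 1 rose and 23 did not pass (mean log2 ratio -0.317). ANPEP, the brush border aminopeptidase N, fell by 1.45 ± 0.07 (SD, n = 3) and HNF4A, a transcription factor of the enterocyte, by 0.85 ± 0.17 (SD, n = 3). TREH, which encodes trehalase, fell by 1.19, though it was well above background on 1 of 3 carnosine arrays, and FABP1, the liver-type fatty acid binding protein, by 0.83 (0.36 by its other probe, which did not pass). The list passed camera without the replicate block (adjusted p = 0.0305) and with it (adjusted p = 0.00428), and on slide 2 alone (adjusted p = 0.00758), but not with an estimated correlation (adjusted p = 0.863 without the block and 0.700 with it). Without the block it did not pass when carnosine 1 (adjusted p = 0.528), control 2 (0.270) or control 3 (0.164) was left out, with array weights (0.0813), no filter (0.0517) or probes bright on all arrays (0.0608). The list mean was then -0.02, -0.07 and -0.22 without those 3 arrays, against -0.66 without control 1 and -0.54 without carnosine 2; with the block and 1 experiment left out it was -0.36 to -0.29. With normexp over all spots the list mean turned to 0.24 (adjusted p = 0.423), where the median of all genes was 0.26; without the 16 smeared spots it did not turn. The ratios of ANPEP, HNF4A and TREH turned positive with all spots too, and not without the smeared ones. Adjusted over the list alone, with the replicate block, 9 genes were lower and 1 higher.

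Goblet cell markers and Paneth and tuft cell markers were lower as lists that passed with the replicate block and did not pass in the fit of all 6 arrays without a block. Of 16 goblet cell markers, 5 fell, among them the trefoil factors TFF3 (-1.06) and TFF2 (-0.86) and the kallikrein KLK1 (-1.06). Camera gave adjusted p = 0.0836 for this list without the replicate block, 0.022 with it and 0.0359 on slide 2; with an estimated correlation the adjusted p was 0.724 and 0.700. Of 7 Paneth and tuft cell markers, ITLN2 (-0.92) and DEFA6 (-1.21, well above background on 2 of 3 carnosine arrays), an intestinal lectin and a defensin, fell, with adjusted p = 0.0779 for the list without the block, 0.00428 with it and 0.00529 on slide 2 (0.724 and 0.700 with an estimated correlation). Of 20 stem cell and Wnt target genes, 6 fell and none rose, including the receptor EPHB2 (-1.76), whose 3 probes all fell, the matrix protein SMOC2 (-1.69) and the R-spondin receptor LGR5 (-0.91). The stem cell and Wnt list did not pass without the block (adjusted p = 0.114) or with it (0.0851), and it passed in 5 of 21 alternatives (adjusted p from 0.012 to 0.438; adjusted p = 0.724 and 0.700 with an estimated correlation). The mean of each of these 3 lists turned positive with normexp over all spots, as did the ratios of TFF2, ITLN2, DEFA6 and LGR5, but not without the smeared spots. In the fit without the block, TFF3 was at 0.00 and TFF2 at 0.51 without carnosine 1, and TFF2 at 0.10 without control 2. Adjusted over the list alone, with the replicate block, 6 goblet cell, 5 Paneth and tuft cell and 6 stem cell genes were lower. The list of 14 enteroendocrine markers did not pass (adjusted p = 0.58), and 2 of its genes rose, CCK (1.14) and VGF (0.64).

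Targets of BMP and TGF-beta signalling were higher as a group. Of 19 measured genes, 6 rose and none fell (mean log2 ratio 0.406; adjusted p = 0.026 without the replicate block, 0.00225 with it and 0.00758 on slide 2). With an estimated correlation the adjusted p was 0.724 without the block and 0.700 with it. Without the block the list did not pass when carnosine 1 (adjusted p = 0.0925), carnosine 2 (0.0542) or control 3 (0.0907) was left out, or with normexp over all spots (0.0539). Its mean was 0.27 without carnosine 1 and with normexp without the smeared spots. Those that rose included NOG, a BMP antagonist, at 1.20 and SKIL, a repressor of SMAD activity, at 0.72; NOG was well above background on 1 control and 2 carnosine arrays. TGFB2, listed among secreted factors, rose by 1.11 ± 0.13 (SD, n = 3). Adjusted over the list alone, with the replicate block, 9 genes were higher.

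The inflammatory list was higher in camera without and with the replicate block, while the immediate early list passed with it but not without it. With the block 12.9% of all genes passed in limma, a share that the 3 immediate early genes that rose, of 24, do not exceed. Of 22 inflammatory and NF-kB response genes, 5 rose and 1 fell (mean 0.335), among them PTGS2, the inducible cyclooxygenase, at 1.15, the cytokine gene IL1B at 1.02 and BIRC3, an inhibitor of apoptosis, at 0.95. The chemokine gene CXCL10 rose by 1.34 and was well above background on 1 control and 2 carnosine arrays. The list passed without the replicate block (adjusted p = 0.026), with it (0.00757) and on slide 2 (0.00758), but not with an estimated correlation (adjusted p = 0.649 and 0.700). The estimates were 0.002 without the block and -0.028 with it, below the preset 0.01, so correlation between its genes does not account for that failure. Without the block it did not pass when carnosine 1 (adjusted p = 0.0925), carnosine 2 (0.0595) or control 3 (0.0907) was left out, or with no filter (0.0517), and its mean was 0.21 with normexp without the smeared spots. Of 24 immediate early genes, CCN1 (1.00), JUN (0.99) and DUSP1 (0.65) rose, with adjusted p = 0.0744 for the list without the block, 0.0306 with it and 0.165 on slide 2; with an estimated correlation the adjusted p was 0.724 and 0.822. With the block it was 0.214 without experiment 1 and 0.0922 without experiment 2. The interferon response list did not pass (adjusted p = 0.905): of 28 genes, 5 rose, such as MX2 (1.04, and 0.19 by its other probe) and IFIT2 (0.95), and 3 fell, such as IFI6 (-0.88) and OAS1 (-0.81, positive with normexp over all spots but not without the smeared spots). Adjusted over each list alone, with the replicate block, 9 inflammatory genes were higher and 2 lower, 3 immediate early genes were higher, and 6 interferon genes were higher and 6 lower.

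DNA replication genes were lower as a group, while cell cycle genes were not. Of 32 DNA replication genes, 8 fell and none rose (mean -0.255), including the DNA ligase LIG1 (-0.91), the replication initiation factor CDC45 (-0.67) and E2F1 (-0.64). Camera gave adjusted p = 0.00119 without the replicate block and 0.00225 with it, 0.164 on slide 2, and with an estimated correlation adjusted p = 0.772 and 0.822. The list did not pass without the block when carnosine 1 (adjusted p = 0.0925) or control 3 (0.0907) was left out, or with it when experiment 1 was (0.222). The means were -0.411 in experiment 1, -0.203 in experiment 2 and -0.152 in experiment 3. Of 26 cell cycle and proliferation genes, none passed with the block, and the list did not pass (adjusted p = 0.842). Adjusted over the list alone, with the replicate block, 13 DNA replication genes were lower and 0 cell cycle genes passed.

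The unfolded protein response list was lower in camera without and with the replicate block, while the cholesterol biosynthesis list passed without it but not with it. Of 21 unfolded protein response genes only 2 fell, where 12.9% of all genes passed in limma with the block. Of 21 unfolded protein response genes, HSPA5, the main endoplasmic reticulum chaperone, fell by 1.14 ± 0.39 (SD, n = 3) and PDIA4 by 0.49; CALR had a log2 ratio of -0.62 and did not pass. The list gave adjusted p = 0.026 without the replicate block, 0.022 with it and 0.164 on slide 2, and adjusted p = 0.649 and 0.700 with an estimated correlation. It did not pass without the block when carnosine 1 (adjusted p = 0.256) or control 3 (0.0969) was left out, or with it when experiment 1 was (0.222). Of 25 cholesterol biosynthesis genes, 6 fell and none rose, with TM7SF2, a sterol reductase, at -1.29, LSS at -0.76 (0.36 by its other probe, which did not pass) and FDPS at -0.69. That list passed without the block (adjusted p = 0.026) but not with it (0.0851) or on slide 2 (0.165), and with an estimated correlation adjusted p was 0.724 and 0.822. Without the block it did not pass when control 1 (adjusted p = 0.0924), carnosine 1 (0.104), carnosine 2 (0.142) or control 3 (0.0977) was left out. Adjusted over each list alone, with the replicate block, 1 unfolded protein response gene and 6 cholesterol genes were lower. For the amino acid and integrated stress response list the adjusted p was 0.434; of 27 genes, NUPR1 (-1.32), PCK2 (-1.16) and CTH (-0.65) fell and ATF3 (0.82) rose, though 1 of its 4 probes gave -0.52.

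**Figure D4:**
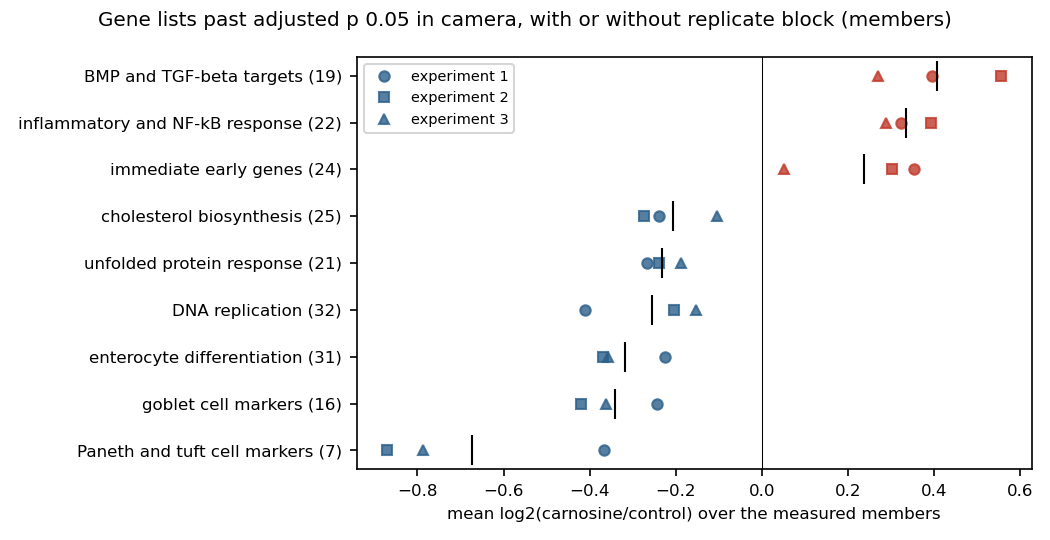
Mean log2 ratio of carnosine to control over the measured genes (number in parentheses) of each list that passed camera with or without the replicate block; symbols (red above 0, blue below) are the 3 experiments and the tick is the mean from the fit without the block. BMP and TGF-beta targets lie highest (0.406), and Paneth and tuft cell markers lie lowest (-0.674). Points of each list lie on the same side of 0 in all 3 experiments.

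Transporters that carry small peptides and amino acids were among the genes that fell. Of 12 measured genes of carnosine and histidine dipeptide handling, 3 fell and none rose. SLC15A1, the intestinal transporter of di- and tripeptides, fell by 0.74 ± 0.05 (SD, n = 3; adjusted p = 0.0191 with the replicate block and 0.475 without). SLC6A6, which carries taurine and beta-alanine, fell by 1.33 ± 0.36, and SLC38A3, a glutamine and histidine carrier, by 1.78 ± 0.28 (SD, n = 3). CNDP2, the cytosolic dipeptidase, had a log2 ratio of -0.02 ± 0.04 (SD, n = 3; adjusted p = 0.877 with the block). CNDP1, the serum carnosinase, was not well above background on the control arrays and at least 1.19-fold higher with carnosine (adjusted p = 0.0602 with the block), its spot in experiment 1 being flagged. This bound rests on the main processing; the ratio of CNDP1 was -0.10 with normexp, with the smeared spots or without them, so its direction stays open. HNMT (0.41 by its brightest probe), SLC15A4 (-0.37), SLC15A3 (-0.12), HDC (-0.13), GADL1 (0.13), SLC36A1 (-0.09) and SLC7A5 (-0.06) did not pass. Of the other 2 probes of HNMT, 1 gave 0.60 and passed (adjusted p = 0.0303 with the block) and 1 gave -0.12 and did not. In the fit without the block the ratios of CNDP2, HDC, GADL1 and SLC7A5 changed sign without control 1, carnosine 2 or carnosine 3, and that of SLC36A1 without control 2. Those of SLC15A3, SLC15A4 and HDC did so with normexp over all spots, but not without the smeared spots. The list, tested on its 11 genes measured on all arrays, did not pass camera without the block (adjusted p = 0.0748) or with it (0.111), and its mean turned positive where flagged spots were kept, in the authors' value table and with normexp over all spots. The other probe of SLC6A6 gave -0.37 and did not pass. Adjusted over the list alone, with the block, 3 genes were lower and 2 higher. Of 29 other nutrient and ion transporters, 3 fell and 3 rose. Among them the cystine and dibasic amino acid carrier SLC7A9 fell by 1.91 ± 0.08, the ascorbate transporter SLC23A1 by 1.83 ± 0.44 and the neutral amino acid carrier SLC43A1 by 1.22 ± 0.22 (SD, n = 3), while the calcium channel TRPV6 rose by 0.89 (well above background on 2 of 3 control arrays; 0.99 by its other probe, which did not pass). This list did not pass (adjusted p = 0.695).

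Enzymes of glucose use changed in both directions. PDK1, a pyruvate dehydrogenase kinase, fell by 1.34 ± 0.23 (SD, n = 3), while PDK4, another kinase of that family, rose by 0.90 ± 0.34 (well above background on 2 of 3 control arrays) and hexokinase HK1 by 0.86 ± 0.06 (SD, n = 3). Of 27 glycolysis genes, 3 rose and 2 fell, and the list did not pass (adjusted p = 0.547). Of 23 genes of fatty acid oxidation and PPARA targets, 1 rose, CREB3L3 (1.45), and 2 fell (adjusted p = 0.647 for the list). Of 33 respiratory chain genes and 40 cytosolic ribosomal protein genes, 0 passed with the replicate block in limma (adjusted p = 0.161 and 0.647 for the lists). In camera the respiratory chain list passed in 3 of 21 alternatives (adjusted p from 2.32e-09 to 0.756) and the ribosomal list in 1. SIRT1 had a log2 ratio of 0.37 ± 0.29 (SD, n = 3; adjusted p = 0.137 with the block) and did not pass. Of 19 genes of sirtuins and mitochondrial biogenesis, NRF1 (-0.58, positive with normexp over all spots but not without the smeared spots) fell (adjusted p = 0.647 for the list). Adjusted over each list alone, with the block, 3 glycolysis genes were higher and 4 lower.

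Secreted neurotrophic and growth factors showed no shared direction. Of 27 measured genes, 3 rose and 3 fell, and the list did not pass (adjusted p = 0.842). NTF3, neurotrophin 3, fell by 0.63 ± 0.11 and GDF15 by 0.71 ± 0.34 (SD, n = 3). The ratios of NTF3 and BDNF turned positive with normexp over all spots, but not without the smeared spots. BDNF had a log2 ratio of -0.05 ± 0.26 (SD, n = 3; adjusted p = 0.817 with the replicate block), and VEGFA -0.38 ± 0.07 (adjusted p = 0.061; 0.09 by its other probe, and 0.14 without the block and control 1). The neurotrophin receptor gene NGFR, listed among neuronal genes, rose by 1.94 ± 0.58 (SD, n = 3). It was well above background on 1 control and 3 carnosine arrays. The neuronal list of 12 genes had a mean of 0.306 and a median of -0.095 and did not pass (adjusted p = 0.647). Adjusted over the list alone, with the block, 3 secreted factors were higher and 4 lower.

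Antioxidant and metal-handling genes did not shift as groups. Of 26 NRF2 targets, 2 fell, ABCC3 (-1.21, and -2.48 by its other probe) and AKR1B10 (-0.81), and none rose (adjusted p = 0.695 for the list). Of 23 antioxidant enzymes, GPX8, a peroxidase of the endoplasmic reticulum, rose by 1.68 ± 0.41 (SD, n = 3) while GSS (-0.57) and GSTM3 (-0.55) were among 3 that fell (adjusted p = 0.802). Of 20 metallothioneins and zinc transporters, SLC30A4 (0.79) was among 2 that rose and SLC39A4 (-0.61, positive with normexp over all spots but not without the smeared spots) fell (adjusted p = 0.776). In the iron handling list of 17 genes, the iron exporter SLC40A1 (0.71) and ID1 (0.60), a regulator of transcription, rose (adjusted p = 0.647 for the list).

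Several other genes changed within lists that did not pass. The circadian regulator BHLHE41 rose by 1.65 ± 0.10 and CRY1 by 0.51 (SD, n = 3); of 19 clock genes, 3 rose (adjusted p = 0.258). DNAJB4 (1.05), HSPB8 (0.84) and HSPA1B (0.54) were the 3 of 20 heat shock genes that rose (adjusted p = 0.161). EGLN3 (0.65), ADM (0.59) and ANGPTL4 (0.55) were the 3 of 23 hypoxia genes that rose (adjusted p = 0.547). TIGAR, a p53 target that acts on fructose bisphosphate, rose by 0.97 (adjusted p = 0.647 for the list of 21). Of 19 replication-dependent histones, 4 rose, such as H2BC5 (0.68), and 2 fell, such as H3C4 (-0.48); their mean was 0.046 and their median -0.06 (adjusted p = 0.647). PARD6B rose by its brighter probe (0.63) and fell by its other (-0.61). Both of its probes passed with the replicate block, so its direction stays open. TJP3 (-0.76) fell among 22 junction genes (adjusted p = 0.161 for the list in camera). FLOT2 (-0.58, and -0.21 by its other probe, which did not pass), SMPD2 (-0.55) and TSPAN8 (0.50) changed among 31 genes of extracellular vesicles (adjusted p = 0.842). ATP6V1H (0.53) rose among 26 autophagy and lysosome genes (adjusted p = 0.722), and NR1I3 (-1.36) was 1 of 2 genes that changed among 24 of drug metabolism (adjusted p = 0.949). The ratios of SMPD2 and NR1I3 turned positive with normexp over all spots, but not without the smeared spots, and that of TSPAN8 was -0.10 in the fit without the block and without control 1.

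Markers of other cell types served as a check for foreign RNA. Of 10 fibroblast markers, 1 rose, TAGLN (1.03), and the list did not pass (adjusted p = 0.566). Of 15 blood and immune markers, CD14 (0.59) and HBA2 (0.58, though 1 of its 3 probes gave 0.01) rose (adjusted p = 0.842). In the fit without the replicate block, no gene of any of the 38 lists passed the threshold over all genes. Of the 38 lists, camera called 6 without the block, 8 with it, 9 with the slide as the block and 5 on slide 2 alone, and 0 with an estimated correlation, with or without the replicate block. Wrong splits of the 6 arrays gave 2 to 12 lists without the block, so a call in that fit is weak ground for a shared change. Fry called 0 lists without the block and 3 with it, the inflammatory, dipeptide handling and circadian clock lists, each at adjusted p = 0.0396. With the slide as the block, the adjusted p was 0.00606 for DNA replication, for BMP and TGF-beta targets and for enterocyte differentiation. It was 0.00663 for the inflammatory list and for Paneth and tuft cell markers, 0.0147 for the unfolded protein response, 0.0246 for goblet cell markers, 0.0328 for cholesterol biosynthesis and 0.0406 for immediate early genes. Adjusted over each list alone, with the replicate block, the remaining lists gave at most 5 genes per direction, except the amino acid and integrated stress response list with 2 higher and 8 lower.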

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

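The fits on the replicate block under other processing, the GC correction and the normexp run without 16 smeared spots were chosen after the data were seen; normexp over all spots was fixed beforehand. WFIKKN1 was the 1 gene that passed without the block, and its adjusted p ranged from 0.00873 to 0.814 over 20 alternatives. The count of 1 gene became 2347 with the replicate block, 2344 with the block and GC correction, 941 with the slide as the block, 570 with array weights, 131 at adjusted p below 0.1 and 17 where probes had to be bright on all 6 arrays. In limma it was 0 on slide 2 alone (2801 at unadjusted p below 0.05), with trend and robust (2215), quantile (2219) and median scaling (1796), no filter (2116), the authors' value table (2175) and single probes (2757). It was also 0 with normexp over all spots (431) or without the smeared spots (1683), and 0 to 0 with each array left out (1361 to 2279), where fewer samples enter. The count of 6 lists ranged with 1 array left out from 0 (without carnosine 1, with 7 at unadjusted p below 0.05, or control 3, with 11) to 10 (without control 1). The number was 15 with normexp over all spots, 11 with the block and GC correction, and 0 with an estimated correlation (2 at unadjusted p below 0.05), with fry (7) and with the block and an estimated correlation (0). The block ended the call of cholesterol biosynthesis and added goblet, Paneth and tuft, and immediate early lists; it changed no other list's call. The count of 2347 became 4504 with trend and robust, 3648 with probes bright on all arrays, 0 with no filter (5249), 0 with normexp over all spots (579) and 3050 without the smeared spots, and 0 (without experiment 2, 4653) to 609 with 1 experiment left out, where fewer samples enter. The 8 lists that passed with the block became 18 with normexp over all spots, 10 without the smeared spots and 5 to 10 with 1 experiment left out. Mean r between experiments, 0.593, was 0.253 with normexp over all spots, 0.667 without the smeared spots, 0.298 with no filter and 0.702 with probes bright on all arrays. The 1036 genes changed alike were 395 with normexp over all spots (201 higher and 194 lower), 475 without the smeared spots (162 higher and 313 lower) and 277 at 2-fold. With normexp over all spots, which moved the median of all genes to 0.26, the means of 5 lists that passed before or after in the fit without the replicate block turned sign: enterocyte differentiation (0.243), antioxidant enzymes (-0.0634), cell cycle (-0.0876), ribosomal proteins (-0.2268) and histones (-0.057). Without the smeared spots none of the 5 turned, and the median of all genes was 0.00. Over all alternatives, single named genes gave 3858 values with 73 changes of sign, and lists gave 797 with 55. Dim probes limit the comparison: 51 genes were not well above background in 1 group and have only a bound.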

Other observations

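The tests with the sign of 1 experiment turned and of the small RNA spread between control arrays were chosen after their results were seen, as were the patterns themselves. Enzymes of amino acid metabolism were lower with carnosine as a list. HAAO, ASL, FAH, GSTZ1 and LDHD had log2 ratios of -2.20, -1.96, -1.47, -1.77 and -1.60, and were singled out after their values were seen. HAAO acts in the breakdown of tryptophan, and FAH and GSTZ1 in that of tyrosine. ASL forms arginine and LDHD acts on lactate, so neither is an enzyme of amino acid breakdown. A list of 34 other measured enzymes, listed under amino acid breakdown, was then written without them. Of these, 10 fell and 0 rose, and 25 of 34 had a ratio below 0. Those that fell included FTCD (-1.71), PRODH (-1.27), IVD (-0.87) and ASS1 (-1.19), which acts in arginine synthesis. The mean of the 34 was -0.343, and it was below 0 in 3 of 3 experiments (-0.304, -0.421 and -0.304). In limma's camera over 3 such lists the adjusted p was 0.000221 with the replicate block and 0.000623 without, and with an estimated correlation the adjusted p = 0.253. With the trend on probe GC content removed, the mean was -0.348. A shared fall of amino acid catabolism may underlie these values, as a hypothesis found and tested on the same arrays.

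TXNIP, ARRDC4, ARRDC3 and KLF10, targets of the glucose-sensing factors MondoA and ChREBP, were higher with carnosine by 1.56, 1.22, 1.03 and 0.69. A shared rise of these targets was tested on 12 others, whose mean was -0.319, the opposite direction (adjusted p = 0.187), with MLXIPL, which encodes ChREBP, at -1.05. KCNQ1OT1 and MRPL23-AS1 lie on the same arm of chromosome 11. The mean absolute ratio of 13 other genes of the region that holds both stood at percentile 75.2 of random lists matched on mean level. A change across the whole region was thus not seen, but a mean over 13 genes cannot exclude a change of part of it. CDKN1C (0.89), LSP1 (0.79) and PHLDA2 (0.58) rose there and SLC22A18AS (-0.97) fell, in the fit with the replicate block. In that fit 12.9% of all genes passed.

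Many genes changed alike in all 3 experiments, and technical explanations were weighed for this. Log2 ratios were lower at higher probe GC content in experiments 1, 2 and 3 (Spearman rho across genes -0.144, -0.229 and -0.208). Among probes of the same gene the slope was -0.00566 per percent GC. With the trend on probe GC content removed, 2344 genes passed with the replicate block, 2018 of them among the 2347 before. The split moved from 1132 higher and 1215 lower to 1002 and 1342, so the trend shifted some calls. The difference between control 3 and control 2, which lie apart along the same slide, correlated with the ratio of experiment 1 at 0.017 across genes, which are not independent replicates. These controls belong to different experiments, whose difference may hide a trend of place, and experiment 1 lay on another slide. The value of 0.017 therefore cannot exclude a trend along the slide. Noise that differs between the experiments would leave similar numbers with 1 sign turned, and the highest was 20 against 1036. These counts follow from the correlation of the experiments (Pearson r from 0.575 to 0.611 across genes) and are not a separate test. A disturbance shared by all pairs could also leave few genes with a sign turned. Each carnosine array lay further along its slide than its control in 3 of 3 pairs, so treatment and place cannot be told apart. No other effect of the place was tested.

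Of the 10 splits of the 6 arrays, 2 gave as many genes as the real one without the block (1 gene, highest other 5) and 6 gave as many lists (6 lists, highest other 12). The splits are too few for a share under 0.05. The split with 5 genes and 12 lists set slide 1 with carnosine 2 against the rest. Setting slide 1 with control 2, control 3 or carnosine 3 against the rest gave 0 genes and 3, 7 and 9 lists. Every split that kept slide 1 together also set an array of slide 2 with it, so none tested the slide alone. These splits gave 1375 to 3584 genes at unadjusted p below 0.05 in limma without the block. The wrong splits that parted slide 1 gave 21 to 268. How far the slide accounts for the 5 genes and 12 lists stays open. Among splits that mixed the slides, control 1, control 2 and carnosine 3 against the rest gave 8 lists. Control 1, control 3 and carnosine 3 against the rest gave 9. With the replicate block, the real split gave 2347 genes and the 3 others that part all 3 pairs gave 0, 0 and 0 in limma, with 21 to 35 genes at unadjusted p below 0.05 without the block. In those 3 splits a change that the pairs share counts as residual spread, so low counts follow from the agreement of the pairs. Patterns that part all pairs are also too few for a share under 0.05.

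Small nuclear and nucleolar RNAs had lower median ratios in experiments 2 and 3 (-0.556 and -0.523) but not in experiment 1 (0.025), over 40 RNAs. The trend with probe GC content did not account for this, since the mean of experiments 2 and 3 was -0.499 with it removed, against -0.539 before. The control arrays of experiments 2 and 3 differed from each other by 0.47 and the carnosine arrays by 0.512, a difference that the arrays of a pair share and that cancels in their ratios. It therefore does not measure the spread within a pair, for which each experiment holds 1 array per group, and that spread stays open. No biological explanation was tested for it.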
